A study of Mus musculus with 2 samples.

How the data were processed

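Invariant natural killer T (iNKT) cells were sorted from epididymal adipose tissue and from spleen of C57BL/6J mice aged 8 weeks, and their RNA was sequenced cell by cell. Per the labels' protocols, adipose tissue was dissociated in collagenase at 1 mg/mL for 25 minutes at 37 degrees, whereas spleens were disrupted mechanically and their red blood cells were lysed. Both suspensions were sorted for live CD45-positive cells that carried the T cell receptor beta chain and bound a CD1d tetramer loaded with PBS57, and that lacked CD19 and F4/80. Per the labels' protocols, libraries were made with 10x Genomics droplet chemistry that reads the 3' end of transcripts. Tissue, dissociation and library therefore differ together between the 2 samples and cannot be told apart. The labels also name a treatment with alpha-galactosylceramide for part of the spleen sample alone. If the spleen values hold that part, treatment cannot be told apart from tissue either. Per the submitters' processing notes, Cell Ranger 3.0.2 and Seurat 3.1.1 were used with the mouse build mm10. The name and settings of the normalization, the filters on cells and any removal of doublets are not given in the sources used here.

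The authors deposited natural log values for single cells in 2 tables, 1 with the cells of both samples and 1 with the adipose cells alone. Undoing the natural log and subtracting 1 gave whole numbers for 100% of the values, within a tolerance of 1e-09. The totals of these whole numbers per cell lay in a narrow range, between 3504 and 5127 for adipose and between 3158 and 5076 for spleen in the table of both samples. They are called corrected counts here, since they are not raw counts of molecules: the same adipose cells had a median total of 4658 in the table of both samples and 6291.5 in the table of adipose cells alone. The 2 tables shared 12783 genes and listed the same adipose barcodes in the same order, and 93.3% of their corrected counts, each rounded to a whole number, were exactly equal, a share that includes values of 0 in both tables. Of the 17.3% of values above 0 in at least 1 of the tables, 61.6% were equal. The original depth of each cell is unknown, so no interval for a level and no thinning of molecules could be computed. Cells were assigned to a sample by the start of their names in the table, and no column was left unassigned.

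The design, the gene lists, the rule for named genes and the other settings planned for comparison were fixed before the data were examined. The design planned a ratio of mean levels for values scaled to a fixed total per cell, and otherwise the difference of mean log values. The values were corrected counts, so the plan called for that difference. Once the unit of the values was seen, a ratio was made the main measure instead, and the planned difference was kept as an alternative. For the ratio, each cell's corrected counts were scaled to a total of 10000. The mean over cells is called the level, in corrected counts per 10000, and the ratio is that of the adipose to the spleen level. With 1 library per group there was no test, no p-value and no error across animals. Genes with a value above 0 in at least 10% of the cells of either sample were compared by size, with a ratio of at least 2-fold counted as higher. Shares of cells carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only, and beside a share of 0 the share that 3 cells would make is given. All deposited cells were used and no doublet caller was run.

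The rule for named genes took the 12 genes with the highest and the 12 with the lowest ratio after adding 0.05 to each level, leaving out genes for ribosomal proteins, mitochondrial genes, antigen receptor segments and genes with provisional names. It also took up to 4 members with the largest ratio in either direction from each gene list, among members detected in at least 5% of the cells of either sample. A fixed set was always to be named: Klrb1c, Zbtb16, Tbx21, Gata3, Rorc, Nfil3, Il10, Ifng, Il4, Xbp1, Cd4 and Cd3e. Clusters were described by the 5 genes with the highest ratio to the other cells among genes detected in at least 25% of the cluster's cells. Of the 438 genes on 41 lists fixed in advance, 391 were in the table of both samples. Il10 is not analysed here. For a list with at least 5 detected members, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean level.

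Clusters were made from 2000 variable genes, scaled values limited to 10, 20 principal components, 15 neighbours and the Leiden method at resolution 0.5 with seed 0. A cluster took the name of a list only if at least 3 of the list's markers were detected in at least 10% of its cells at 2-fold or more over the other cells, if the list's mean level was highest in that cluster, and if no other list had as many markers among its top 10 genes. The markers were fixed in advance, and this rule for names was set after the data were examined. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Gene coordinates were taken from the GENCODE annotation of GRCm38, the assembly that mm10 also names.

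The steps were tested on simulated data. For the comparison of adipose with spleen over 13603 genes, with 500 simulated cells per sample, genes set to ratios of 0.25, 0.5, 2 and 4 returned median ratios of 0.245, 0.496, 1.97 and 4.14, and 98.4% of 5584 unchanged genes lay within 1.5-fold of no difference. For the gene lists of that comparison, 0 of 25 unchanged lists, scored on the 5584 unchanged genes, lay outside the central 95% of random lists. A list of 15 genes raised 4-fold, scored on 5784 genes, lay at percentile 100. The simulated genes varied independently around 1 shared profile, whereas the lists of the data drew on 7603 genes. The simulation therefore cannot show how often lists of genes that vary together leave that range. For the clusters of adipose cells, run on 12933 genes, 3 simulated kinds among 1000 cells were returned as 3 clusters with an adjusted Rand index of 1.

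Alternatives planned in advance covered the scaling, the detection limit, the size threshold, the pseudocount, the summary of a list, the cells used and the settings of the clustering. Added after the data were examined were summed corrected counts, each cell thinned to 3000 corrected counts, the removal of cells with markers of lineages outside T cells, natural killer cells and innate lymphoid cells, and the removal of the cycling, the iNKT17-like or the interferon-stimulated cluster of the joint clustering. The comparison of untreated with treated spleen cells was left out because the cell names carry no hashtag and 0 features of the table were hashtags.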

Results

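Gene expression was measured in single iNKT cells, T cells with a semi-invariant receptor for lipid antigens presented by CD1d, from epididymal adipose tissue and from spleen. The adipose library held 3004 cells and the spleen library 5952 cells. Per the labels, the spleen library pooled cells of saline-treated mice with cells of mice treated for 4 hours with 1 µg of alpha-galactosylceramide, a lipid agonist of iNKT cells. Whether the spleen values used here hold both parts is not given in the sources used here, and cells could not be assigned to them, so spleen is taken as 1 sample of unknown makeup, and untreated against treated spleen is not analysed here. With 1 library per tissue there were no replicates, and each difference describes these 2 libraries. The median corrected total per cell was 4658 in adipose and 3827 in spleen, and the median number of detected genes per cell was 1989 and 1491. Transcripts for ribosomal proteins and from the mitochondrial genome made up 26.6% of the adipose and 34.7% of the spleen corrected counts.

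The main comparison asked how iNKT cells of adipose tissue differ in expression from those of spleen. Adipose iNKT cells had higher levels of the signal-induced nuclear receptor gene Nr4a2, at 70.0-fold the spleen level, of the kinase gene Stk32c, at 218-fold, and of Spry2, an inhibitor of growth factor receptor signalling, at 45.7-fold. Spleen iNKT cells had higher levels of Dtx1, a Notch pathway ubiquitin ligase, at 145-fold the adipose level, and of the chemokine receptor gene Ccr9, at 66.4-fold. The sizes of these ratios are imprecise, since the lower level lay near 0. Stk32c was above 0 in 14, Nr4a2 in 52 and Spry2 in 107 of 5952 spleen cells, and Dtx1 in 18 and Ccr9 in 24 of 3004 adipose cells. Of the natural killer cell genes 5 of 6 were at least 2-fold higher in adipose, of the killer lectin receptors 8 of 13 and of the immediate early genes 11 of 16, whereas 4 of 10 interferon-stimulated genes and 3 of 8 genes of naive or central memory T cells were at least 2-fold higher in spleen. Of 5784 genes compared, 514 were at least 2-fold higher in adipose, 101 at least 2-fold higher in spleen, and 5169 within 2-fold. With the difference of mean log values, the measure planned for values not scaled to a fixed total, 30 and 5 of the same genes passed 2-fold. The median gene had a log2 ratio of 0.21. Relative to that median gene, 375 genes were at least 2-fold higher in adipose and 147 in spleen, so that the adipose share of these genes was 71.8% in place of 83.6%.

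Among the other genes with the largest ratio toward adipose, the level of Vim, an intermediate filament gene, was 11.1 corrected counts per 10000 in adipose and 0.484 in spleen, and that of the calcium-binding protein gene S100a4 was 12.1 and 0.641. The phospholipid-binding protein gene Anxa2 was 29.1-fold higher in adipose, and Tnfaip3, an inhibitor of NF-κB signalling, was 20.6-fold higher. Metrnl, which encodes a secreted protein, was 54.6-fold higher, the chemokine receptor gene Cxcr4 32.7-fold and Ier5l 108-fold, the last with 16 of 5952 spleen cells above 0. The inhibitory receptor genes Klra7 and Klrg1 were 39.5-fold and 27.4-fold higher, with the caveat that Klra genes are near-identical copies between which reads can be misassigned. Toward spleen, Il7r, the interleukin-7 receptor alpha chain gene, had levels of 9.12 in spleen and 1.72 in adipose, and the creatine kinase gene Ckb had levels of 4.32 and 0.839. Art2b, an ADP-ribosyltransferase gene, was 7.19-fold higher in spleen, the phospholipid flippase gene Atp8a2 6.64-fold, Bzw2 4.95-fold, AW011738 7.83-fold, Abi3 6.04-fold and the death receptor gene Tnfrsf25 4.57-fold. Abi3 was above 0 in 17.6% of the other spleen cells and 14.0% (95% interval 5.30 to 27.9) of a small spleen cluster with B cell and myeloid genes, and was not separated from it. Ctss, a lysosomal protease gene of antigen-presenting cells, was 6.51-fold higher in spleen, and its level was 5.84 in that cluster against 0.36 in the other spleen cells.

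**Figure D1:**
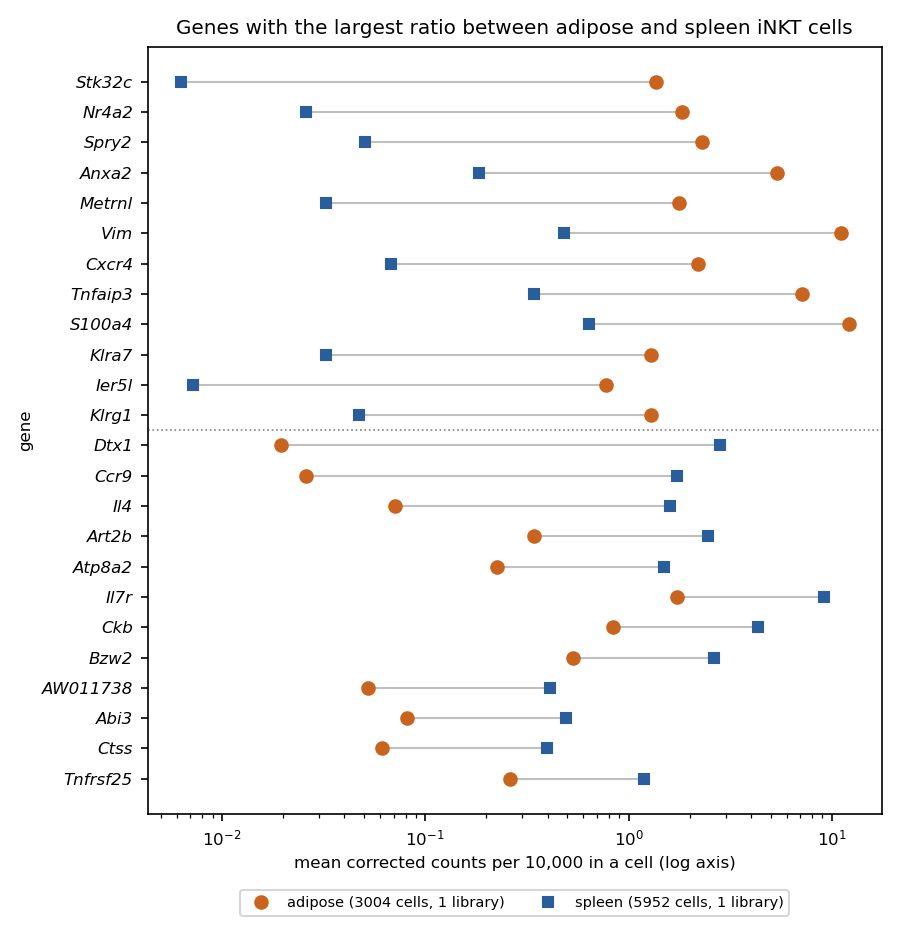
Mean level of the 12 genes with the largest ratio toward adipose (above the dotted line) and the 12 with the largest ratio toward spleen, on a log axis in corrected counts per 10000; each point is the mean over the cells of 1 library and no error across animals can be given. Stk32c has the widest gap toward adipose (218-fold) and Dtx1 toward spleen (145-fold), sizes that are imprecise since only 14 spleen and 18 adipose cells, respectively, were above 0.

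Stk32c, Nr4a2, Dtx1 and Ccr9 are each annotated as protein coding in GRCm38. Stk32c spans positions 139103638 to 139213307 of chromosome 7 on the minus strand, and Nr4a2 spans 57106830 to 57124003 of chromosome 2 on the minus strand. Dtx1 spans 120680202 to 120711927 of chromosome 5 on the minus strand, and Ccr9 spans 123678439 to 123784330 of chromosome 9 on the plus strand.

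Of the genes named in advance for iNKT subsets, Nfil3, a transcription factor gene linked to regulatory iNKT cells, was 71.8-fold higher in adipose, with levels of 0.629 and 0.00875. The level of Tbx21, the T-bet gene of the interferon-producing subset iNKT1, was 1.31 in adipose and 0.935 in spleen, and that of Zbtb16, which encodes the lineage factor PLZF, was 0.411 and 0.636. Zbtb16 was above 0 in 21.4% of the other spleen cells and 11.6% (3.89 to 25.1) of the B cell and myeloid cluster, which did not separate the shares. Gata3 had levels of 1.40 and 1.38 and Rorc, the RORγt gene of the subset iNKT17, had levels of 0.0793 and 0.051. The direction of Gata3 turned when scaled to the median gene, and that of Rorc when cells with markers of other cell types were left out. That filter left 1091 of 3004 adipose and 3297 of 5952 spleen cells. It counts Il2ra, Ikzf2 and Capg, which were raised in the iNKT17-like cluster of adipose cells, so it can remove such cells themselves. Rorc also turned, at a log2 ratio of -5.05, without the iNKT17-like cluster, a removal that took cells from adipose alone. Ifng had levels of 3.17 in adipose and 2.45 in spleen, and Xbp1, a transcription factor gene of the unfolded protein response, had levels of 0.793 and 0.587. The level of Cd4 was 0.263 in adipose and 0.509 in spleen, where its share of 17.2% was not separated from the 6.98% (1.46 to 19.1) of the B cell and myeloid cluster, and that of the T cell receptor subunit gene Cd3e was 3.65 and 4.70. Klrb1c, which encodes NK1.1, was above 0 in 44.2% of adipose cells (95% interval 42.5 to 46.0) and 46.9% of spleen cells (45.7 to 48.2), against 6.98% (1.46 to 19.1) of the 43 spleen cells of the B cell and myeloid cluster. After each cell was thinned to 3000 corrected counts, the Klrb1c shares were 34.4% and 40.4%.

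Il4, the signature cytokine gene of the subset iNKT2, had a level of 1.61 in spleen and 0.0707 in adipose, a 22.7-fold difference. It was above 0 in 40.0% of the other spleen cells (38.7 to 41.3) and in 41.9% (27.0 to 57.9) of the cells of the B cell and myeloid cluster, in which it should be absent. The spleen Il4 share did not exceed this background, so it is not read as expression by spleen iNKT cells, nor is such expression excluded. Over the 6 other spleen clusters of at least 20 cells it ran from 28.6% to 53.5%, the latter in the cluster with the most detected genes per cell, a median of 2271. Il13 was above 0 in 7.77% and 11.6% and Ccl4 in 43.2% and 44.2% of the same cells, which did not separate them either, and myeloid cells can express Ccl4 themselves. Lta was above 0 in 5.91% of the other spleen cells and 4.65% (0.568 to 15.8) of that cluster, which did not separate the shares. Whether the cells of that cluster express Lta themselves was not tested. Cd3e was above 0 in 78.6% of the other spleen cells and 18.6% of that cluster, and Ifng in 50.8% and 27.9%. Other T cell transcripts were found in most of the 43 cells, with Cd3d in 69.8% and Cd3g in 74.4% of them against 98.9% and 99.6% of the other spleen cells, and their mean levels were 0.223 and 0.214 times those of the other cells. Among the named genes at least 2-fold higher in spleen, the share in the other spleen cells lay above the 95% interval of the B cell and myeloid cluster for 16 genes and did not for 14, an interval that is wide with 43 cells. These 14 included Ctss, Ighm and Pecam1, with higher shares in that cluster, and mt-Cytb, found in 100% of both. The median number of detected genes was 1491 in the other spleen cells and 1279 in that cluster.

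**Figure D2:**
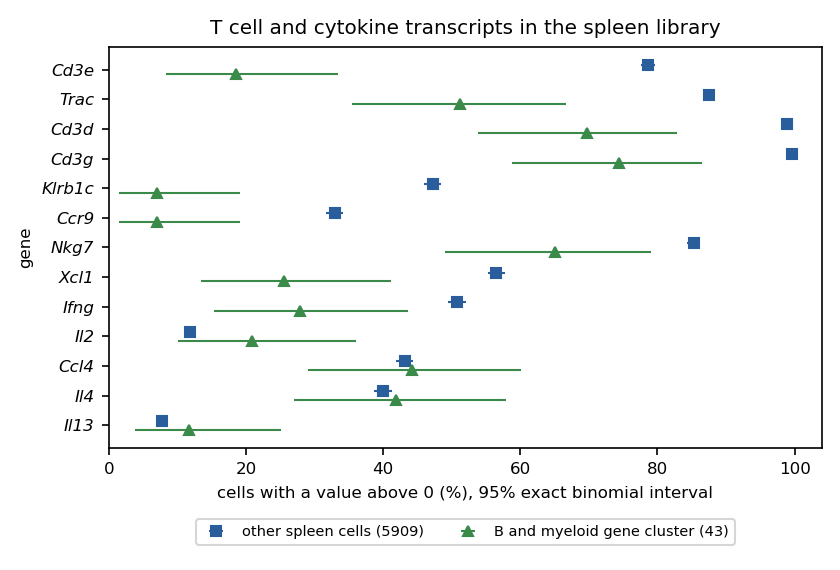
Share of spleen cells with a value above 0, in percent with exact 95% binomial intervals that cover counting error only, for 13 genes in the 43 cells of the B cell and myeloid cluster (triangles) and in the other spleen cells (squares). Cd3e, Klrb1c and Ccr9 lie far apart in the cell groups, Cd3g (74.4% and 99.6%) lies high in both, whereas Il4 (41.9% and 40.0%) and Ccl4 (44.2% and 43.2%) overlap.

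Of 16 detected iNKT1 genes, 4 were at least 2-fold higher in adipose and 1 in spleen. Ly6c2 was 9.20-fold, the killer lectin receptor gene Klre1 4.12-fold and the death ligand gene Fasl 3.04-fold higher in adipose, and the transcription factor gene Id2 was 2.44-fold higher in spleen. Of 5 detected iNKT17 genes, 4 were higher in adipose, with Tmem176b at 6.55-fold, Tmem176a at 5.12-fold, the leukotriene receptor gene Ltb4r1 at 5.36-fold and Serpinb1a at 3.64-fold. Without the iNKT17-like cluster of 283 adipose and 0 spleen cells, which these genes helped to form, the log2 ratios were 0.39, -0.019, 0.016 and -0.29. The ratios had to fall, since the removal took the cells rich in these genes from adipose alone. They compare the other adipose cells with all spleen cells. Of 10 detected iNKT2 genes, 4 were higher in spleen and 1 in adipose. Apart from Il4 and Il13, they were Slamf6, at 4.48-fold, and Il17rb, a receptor gene for interleukin-25, at 4.04-fold. Slamf6 was above 0 in 26.2% of the other spleen cells and 25.6% (13.5 to 41.2) of the B cell and myeloid cluster. Il17rb was so in 9.19% and 2.33% (0.0589 to 12.3), so neither pooled share was separated from that cluster. In 1 joint cluster of 768 spleen and 5 adipose cells, which these genes helped to form, the shares were 60.3% and 30.4%. Both lay above those intervals, whereas the Il4 share of no spleen T cell cluster lay above its own interval. Of 6 detected genes linked to regulatory iNKT10 cells, 2 were higher in adipose, Nfil3 and the inhibitory receptor gene Ctla4, the latter at 39.2-fold, while Prdm1 and Icos were within 2-fold. Of the follicular helper list, 2 genes were detected: Sh2d1a was 2.08-fold higher in spleen and Pdcd1 was within 2-fold. Of 8 naive and central memory genes, 3 were higher in spleen, Ccr9, Il7r and the chromatin organiser gene Satb1 at 2.15-fold, whereas Tcf7 was within 2-fold with a level of 1.28 in adipose and 0.742 in spleen.

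Of 6 detected natural killer cell genes, 5 were at least 2-fold higher in adipose. The granzyme gene Gzmb was 13.5-fold higher, and the signalling adaptor genes Fcer1g and Tyrobp were 12.9-fold and 8.80-fold higher. When cells with at least 2 markers of another cell type were left out, a filter that uses these genes themselves, the log2 ratio of Gzmb was 2.64 and that of Tyrobp 0.90, below 2-fold. Of 13 detected killer lectin receptor genes, 8 were higher in adipose and 0 in spleen, among them Klra5 at 15.4-fold and Klra1 with levels of 2.94 and 0.196. Of 9 cytotoxicity genes, 4 were higher in adipose, among them the protease inhibitor genes Serpinb9 at 5.06-fold and Serpinb6b at 2.24-fold. Of 13 tissue residency genes, 8 were higher in adipose and 1 in spleen, with Rgs2 at 12.1-fold, the transcription factor genes Crem and Bhlhe40 at 7.47-fold and 4.82-fold, and the collagen-binding integrin gene Itga1 at 5.73-fold. Of 7 recirculation genes, 3 were also higher in adipose, Ly6c2, Emp3 at 3.40-fold and the lysophospholipid receptor gene S1pr4 at 2.17-fold, while Klf3 was within 2-fold.

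Of 16 detected immediate early genes, 11 were at least 2-fold higher in adipose and 0 in spleen, and 8 were so relative to the median gene. The phosphatase gene Dusp1 was 12.1-fold higher, and the transcription factor genes Fos, Fosl2 and Klf6 were 11.9-fold, 10.2-fold and 6.46-fold higher. Only the adipose sample was digested with collagenase at 37 degrees. Of 15 T cell receptor response genes, 7 were higher in adipose and 1 in spleen, with Nr4a1 at 7.74-fold, Nr4a3 at 5.88-fold and the activation marker gene Cd69 at 3.23-fold. Of 8 heat shock genes, Hsph1 was 2.11-fold higher in adipose and the other 7 were within 2-fold, and none was 2-fold higher relative to the median gene, such as Hspa8 with levels of 21.3 and 14.6 and Hspe1 with levels of 2.37 and 3.48. Of 21 genes of endoplasmic reticulum stress, 20 were within 2-fold, and Dnajb9 was 2.66-fold higher in adipose. Of 13 cytokine and chemokine genes, 2 were higher in adipose, among them Xcl1 at 2.31-fold, and 4 in spleen, among them Il4, Il13 and Lta, the latter at 2.87-fold, whose spleen shares were not separated from those of the B cell and myeloid cluster. Relative to the median gene, 0 of these 13 were higher in adipose. The median log2 ratio of this cytokine list was 0.37 and its mean was -0.54, which differ in sign. Of 15 cytokine receptor genes, 5 were higher in adipose, with Il10ra at 5.74-fold, Il21r at 5.24-fold and Ifngr1 at 4.78-fold, and Il7r was higher in spleen.

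Of 10 interferon-stimulated genes, 4 were at least 2-fold higher in spleen and 0 in adipose, with Ly6a at 3.60-fold, the signal transducer gene Stat1 at 2.81-fold, Ifit1 at 2.77-fold and Rtp4 at 2.30-fold. Without a cluster like interferon-stimulated cells, 1 from adipose and 112 from spleen, the log2 ratio of Ifit1 was -0.66, within 2-fold, and those of Ly6a, Stat1 and Rtp4 were -1.80, -1.42 and -1.03. Ifit1 was above 0 in 6.97% of the other spleen cells and 4.65% (0.568 to 15.8) of the B cell and myeloid cluster. Rtp4 was so in 15.2% and 14.0% (5.30 to 27.9), and these pooled shares did not separate them. In the cluster like interferon-stimulated cells, which Ifit1 helped to form, its share was 74.3% at a level of 8.93, above that interval. Both are genes that other cell types can express. Whether the treatment of part of the spleen sample raised the interferon-stimulated genes could not be tested, since cells could not be assigned to it. Of 9 detected cell cycle genes, 6 were higher in adipose, with the proliferation marker gene Mki67 at 13.1-fold, the microtubule regulator gene Stmn1 at 12.3-fold and the topoisomerase gene Top2a at 9.17-fold. Without the cells of a cycling-like cluster, 140 from adipose and 8 from spleen, their log2 ratios were 1.76, 1.25 and 1.20. Of 15 genes of cholesterol and fatty acid synthesis, 5 were higher in adipose, among them Sqle at 6.04-fold and Insig1 at 3.07-fold, and Scd2 was 2.59-fold higher in spleen, while relative to the median gene 2 were higher in adipose. Scd2 was above 0 in 9.29% of the other spleen cells and 11.6% (3.89 to 25.1) of the B cell and myeloid cluster, which it did not exceed. Of 10 genes of fatty acid uptake and oxidation, 3 were higher in adipose, the fatty acid carrier gene Fabp5 at 5.47-fold, the carnitine transferase gene Cpt1a at 4.91-fold and the lipid droplet coat gene Plin2 at 2.81-fold. Of 14 glycolysis genes, 3 were higher in adipose, with the glucose transporter gene Slc2a1 at 2.53-fold, Eno1 at 2.34-fold and Tpi1 at 2.13-fold. Of 12 mitochondrially encoded genes, mt-Cytb was 2.16-fold higher in spleen and the other 11 were within 2-fold. Of 12 genes of apoptosis and survival, 7 were higher in adipose, including both the death-promoting Bcl2l11 and Bbc3, at 4.79-fold and 3.71-fold, and the survival gene Bcl2, at 2.25-fold, and relative to the median gene 4 were higher. Of 5 checkpoint receptor list genes, 3 were higher in adipose, Ctla4, the ectonucleotidase gene Entpd1 at 3.46-fold and Tox at 2.21-fold, and Cd160 was 2.33-fold higher in spleen. Of 7 genes of the adipose regulatory T cell signature, 2 were higher in adipose, Klrg1 and Ctla4, and Tnfrsf9 was 2.17-fold higher in spleen, where its share of 9.97% was not separated from the 4.65% (0.568 to 15.8) of the B cell and myeloid cluster. The 12 general T cell genes were all within 2-fold, such as Lck with levels of 3.09 and 5.22 and Cd2 with levels of 4.29 and 2.28.

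Of 26 lists with at least 5 detected members, 16 had a median above and 4 a median below the central 95% of random lists of matched level, as a description of these 2 libraries. Genes such as Klrg1, Gzmb, Fasl, Ly6c2 and Ctla4 each stand on more than 1 list, so these counts are not of separate programs. The largest medians were those of the natural killer cell list, at a log2 ratio of 3.72, and of the iNKT17 list, at 2.36. Without the iNKT17-like cluster the median of the iNKT17 list was -0.019, inside the range of random lists. That removal took cells from adipose alone, chosen partly on these genes, so a fall was fixed in advance. The 4 lists below the range were iNKT2, at -0.89 with Il4 and Il13 among its members, interferon-stimulated genes, at -0.56, mitochondrially encoded genes, at -0.46, and naive and central memory genes, at -0.44. Relative to the median gene, Trav11, Hsph1, Xcl1, Serpinb6b, S1pr4, Tpi1, Bcl2 and Tox were within 2-fold, whereas Cd4, at a log2 ratio of -1.17, and Klf3, at -1.15, were over 2-fold higher in spleen. In the iNKT2 list 6 genes in place of 4 were then higher in spleen, and in the mitochondrially encoded list 2 in place of 1. Klf3 was above 0 in 49.1% of the other spleen cells and 41.9% (27.0 to 57.9) of the B cell and myeloid cluster, which did not separate the shares. Without cells with at least 2 markers of another cell type, Capg, at a log2 ratio of 0.91, Sh2d1a, at -0.96, Ighm, at -0.94, Serpinb6b, at 0.92, and Hsph1, at 0.97, were also within 2-fold, the ratios of Klre1, Tmem176b, Tmem176a and Ltb4r1 were 1.11, 1.22, 1.03 and 1.45, and that of Il7r was -3.83. The filter on markers of other cell types can itself remove iNKT17-like cells, as stated above. Without the iNKT17-like cluster, again a removal from adipose alone, the ratios of Il7r, Ckb, Tnfrsf25 and Ctss were -3.59, -3.41, -2.83 and -4.32. Those of Il17rb, Lta and Pecam1 were then -4.42, -2.70 and -1.88, that of Capg was 1.28, that of Il2ra was -2.19, and Sh2d1a, at -0.98, was within 2-fold.

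**Figure D3:**
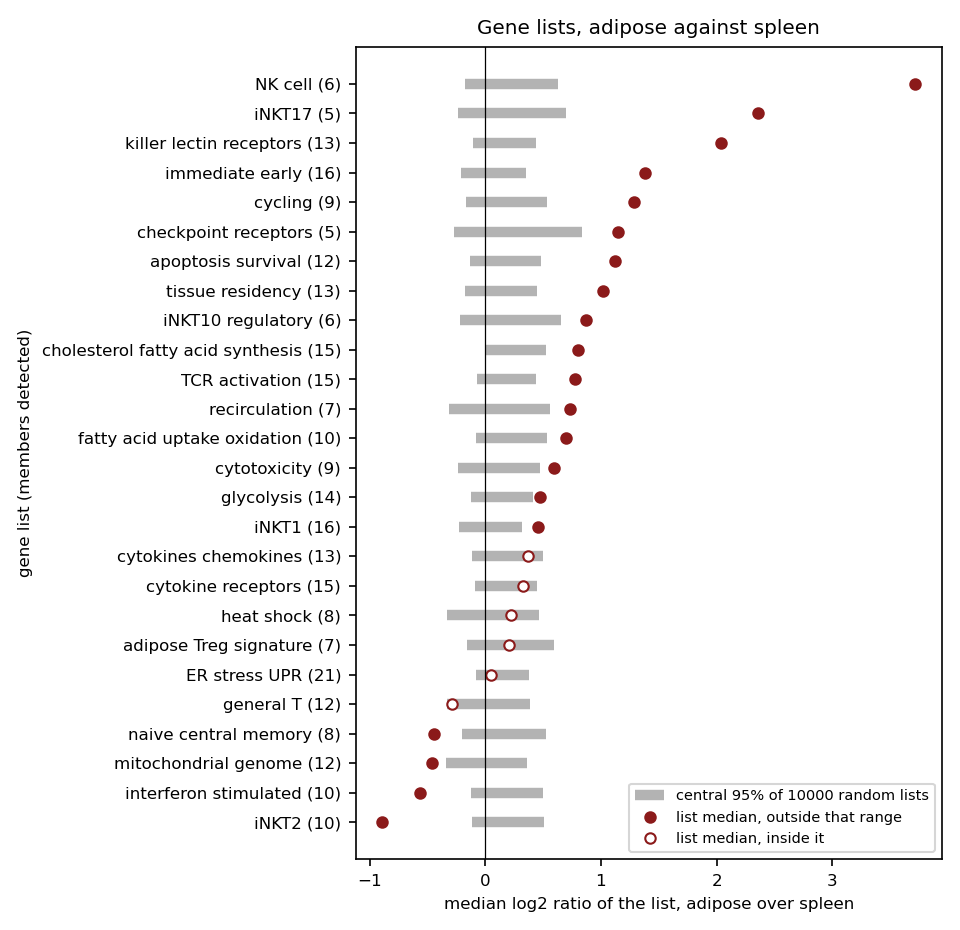
Median log2 ratio of adipose over spleen for 26 gene lists with at least 5 detected members (number in brackets), each beside the central 95% of 10000 random lists of the same size and level (grey bars). Filled points lie outside the bar: 16 lists to its right and 4 to its left, and the natural killer cell list lies farthest to the right, at 3.72.

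The sort selected on the T cell receptor and the tetramer and against CD19 and F4/80. At least 2 markers of a lineage outside T cells, natural killer cells and innate lymphoid cells were found in 2.66% of adipose cells (2.12 to 3.30) and 3.34% of spleen cells (2.90 to 3.83). B cell markers of this number were found in 0.20% and 1.93% of cells, macrophage or monocyte markers in 1.93% and 0.924%, dendritic cell markers in 0.366% and 0.823%, and neutrophil markers in 0.166% and 0.37%. The macrophage or monocyte marker Cst3 alone was above 0 in 49.5% of adipose and 34.7% of spleen cells. With at least 3 markers, the macrophage or monocyte count turned direction, at 1 adipose and 13 spleen cells. Any of these lineages was then found in 3 adipose and 47 spleen cells. Stromal or adipocyte markers and endothelial markers were each found in 1 cell per sample, platelet and mast cell or basophil markers in 0 cells, where 3 cells would be a share of 0.0999% in adipose and 0.0504% in spleen, and erythroid markers are not analysed here. Counting every list of another cell type gave 63.7% and 44.6%, and some markers, such as Klrg1 and Il2ra, stand on more than 1 list. Natural killer cell genes were found in 39.8% and 4.00% of cells, regulatory T cell genes in 28.1% and 35.4%, γδ T cell genes in 13.1% and 6.10%, genes of group 2 innate lymphoid cells in 31 and 89 cells, and CD8 T cell genes in 0.133% and 0.319%. At the level of genes, Ighm was 2.15-fold and Pecam1 2.43-fold higher in spleen, Mmp9 was 3.41-fold higher in adipose, and Cst3 was within 2-fold and turned direction with the scaling. Of the regulatory T cell list, Capg was 4.04-fold higher in adipose, Ikzf2 was 3.87-fold higher in spleen, and Il2ra and Tnfrsf18 were within 2-fold. The receptor segment gene Trav11 was 2.32-fold higher in adipose, and the γδ receptor genes Tcrg-C1 and Tcrg-C2 were within 2-fold, the former turning direction with the scaling.

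The states of adipose iNKT cells were examined in the table of adipose cells alone. A cluster of 287 cells, 9.55% of the sample (8.53 to 10.7), was iNKT17-like, and a cluster of 194 cells, 6.46% (5.61 to 7.40), was cycling-like. The iNKT17-like cluster was defined by Pxdc1, Tmem176a, Tmem176b, Ltb4r1 and Igf1r, and the cycling-like cluster by Stmn1, Pclaf, Hist1h1b, Ube2c and Birc5. The remaining clusters took no list's name. They held 1007 cells defined by Klrg1, Stk32c, Ccl5, Ccdc136 and Plac8, 846 cells (28.2% of the sample) defined by Klrc1, Klrc2, Klrd1, Tyrobp and Cd9, with 5 markers of iNKT1 and 4 of natural killer cells, 604 cells defined by Nav2, Cd244, Gas7, Klrg1 and Gzmb, and 66 cells defined by Tnfrsf9, Csf2, Ccl4, Irf8 and Marcksl1. Klrg1 was a defining gene of both the 1007 and the 604 cells. The median number of detected genes was the lowest of the clusters in the former, at 1880, and the highest in the latter, at 2773.5. Whether the number of detected genes separated these cells was not tested. Across the 6 clusters the level of Icos, a costimulatory receptor gene, was 9.13 in the iNKT17-like cluster and between 1.48 and 2.89 in the others. Zbtb16 was at 1.07 in the iNKT17-like cluster and 1.13 in the cluster of 66 cells, and between 0.215 and 0.371 in the rest. The mean level of the cytokine list was 0.486 in the iNKT17-like cluster and 7.50 in the cluster of 66 cells, and Xcl1 had levels of 0.447 and 42.4 there. Nfil3 lay between 0.296 and 0.672 in all 6 clusters. The same genes took part in forming the clusters, so these levels describe the clusters and do not test them.

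**Figure D4:**
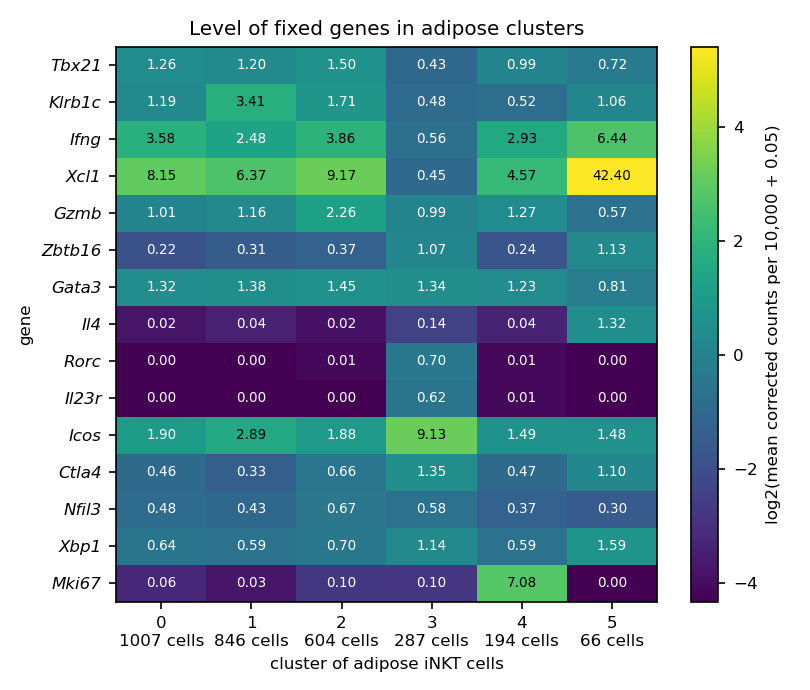
Mean level of 15 genes in the 6 clusters of adipose iNKT cells, with the level in corrected counts per 10000 printed in each field and coloured by log2 of the level plus 0.05. Rorc (0.696) and Icos (9.13) are highest in cluster 3, which is iNKT17-like, Mki67 (7.08) in cluster 4, which is cycling-like, and Xcl1 (42.4) in cluster 5.

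When cells of both tissues were clustered together, each of 11 clusters drew over 90% of its cells from 1 sample, so cluster and library cannot be told apart. Such clusters were 8 of 9 with 30 principal components, 9 of 10 with seed 1 and 14 of 15 at resolution 1.0. The iNKT17-like cluster held 283 adipose and 0 spleen cells, which sets no limit on the share of such cells in spleen, because clusters followed the libraries. A cluster of 768 spleen and 5 adipose cells carried 3 iNKT17 markers, Rorc, Serpinb1a and Il18r1, beside 6 of iNKT2 and 5 of naive or central memory T cells, and took no name. Rorc was above 0 in 1.88% of spleen cells and 3.56% of adipose cells, and in 0 of the 43 cells of the B cell and myeloid cluster, too few to set a background for it. A cycling-like cluster held 140 adipose and 8 spleen cells, 1.65% of all cells, but this split depended on the settings, since the cluster with the highest cell cycle list held 1.03% with 10 principal components and 3.90% with 30, where it was not over 90% from 1 sample. A cluster like interferon-stimulated cells held 1 adipose and 112 spleen cells. The 43 spleen cells defined by Lyz2, Cd74, H2-Eb1, Igkc and H2-Aa, 0.722% of the sample (0.523 to 0.972), formed the B cell and myeloid cluster.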

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

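The alternatives with summed corrected counts, thinning to 3000 corrected counts, the removal of cells with markers of lineages outside T cells, natural killer cells and innate lymphoid cells, and the removal of the cycling, iNKT17-like or interferon-stimulated joint cluster were chosen after seeing the data. Of the values recomputed for counts, shares and clusters, 93 stayed within 1.5 times the main count or within the 95% interval of the main share, and 19 moved. Of the named genes at 2-fold or more, Tmem176a and Serpinb1a changed direction, with log2 ratios of -0.019 and -0.29 without the iNKT17-like cluster, as did the median of the iNKT17 list, at -0.019, since these genes helped to form that cluster of adipose cells. No other named gene at 2-fold and no other list outside the range of random lists changed direction, though Tyrobp, Capg, Sh2d1a, Ighm, Serpinb6b and Hsph1 were within 2-fold without cells with markers of any other cell type, Tmem176b, Ltb4r1 and Sh2d1a without the iNKT17-like cluster, and Ifit1 without the interferon-stimulated cluster. Scaled without ribosomal protein and mitochondrial genes, Tpi1, S1pr4, Tox, Hsph1 and Hmgb2 were also within 2-fold, at log2 ratios of 0.94, 0.93, 0.98, 0.91 and 0.97. Hmgb2, of the cell cycle list, was so without the cycling cluster too, at 0.86. Gata3, Rorc, Cst3 and Tcrg-C1, all within 2-fold, changed direction under at least 1 alternative. The medians of the cytokine, endoplasmic reticulum stress and adipose regulatory T cell lists, which lay inside the range of random lists, did so as well. With the difference of mean log values, 30 genes passed 2-fold toward adipose and 5 toward spleen, and 6 of the 24 named genes were shared. That measure compresses ratios of low levels by its construction. Requiring detection in 25% of cells left 2685 genes, of which 223 and 51 passed, and requiring 3-fold left 236 and 35, both being stricter by construction. With a pseudocount of 0.25, 14 of the 24 named genes were shared; the cause was not tested. Requiring 3 markers of any other cell type gave 30.03% of adipose and 8.32% of spleen cells. At least 2 markers of the lineages outside T cells, natural killer cells and innate lymphoid cells alone gave 2.66% and 3.34%. Both rules are narrower by construction. The Klrb1c share was 48.4% in the table of adipose cells alone. The same cells had a higher median corrected total there, 6291.5 against 4658, though the cause of the higher share was not tested. After thinning, the share was 34.4% in adipose and 40.4% in spleen, since fewer counts per cell leave fewer cells above 0. Resolution 1.0 gave 10 adipose clusters, and resolution 0.25 gave 6 joint clusters, with 6 of them over 90% from 1 sample. Without receptor segment genes the cycling-like share was 7.86%; the cause was not tested. Among named genes at 2-fold or more, 862 values stayed within 1.5-fold and 126 moved, and among lists 290 stayed and 21 moved; 105 of these moves came from the difference of mean log values. No paired analysis was possible because each group has 1 sample and no result comes from a test. Thinning of molecules and ratios of pooled counts of molecules were not run because the original counts are unknown, nor were pooled sums for the treated and untreated spleen parts because cells could not be assigned, and the depth behind the corrected counts sets no computable limit here.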

Other observations

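The tests of collagenase digestion, of the scaling, of natural killer cells inside the gate and of free RNA were chosen only after the result was seen, as were the genes named in this part. The 66 adipose cells defined by Tnfrsf9, Csf2 and Ccl4, 2.20% of the sample (1.70 to 2.79), also had the highest mean of the heat shock list, at 9.43 corrected counts per 10000 against 3.92 to 5.67 in the other adipose clusters. The chaperone gene Hspd1 had a level of 6.31 there and 1.27 to 2.60 elsewhere, and Hspa5, the main chaperone gene of the endoplasmic reticulum, 9.40 and 4.19 to 4.63. The mean of the endoplasmic reticulum stress list was 2.23 against 1.27 to 1.55. Il4 had a level of 1.32 in these cells and 0.0193 to 0.137 in the other adipose clusters.

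In the joint clustering, a group of 234 spleen and 5 adipose cells had a mean level of the natural killer cell list of 1.43, against 1.14 in the adipose cluster led by Fcer1g and Tyrobp and 0.0291 to 0.174 in the other spleen clusters of T cells, and 1.45 in the B cell and myeloid cluster. The list genes at 2-fold or more over other cells were Gzma, Gzmb and Fcer1g in the spleen group. In that adipose cluster they were Ncr1, Gzmb, Tyrobp and Fcer1g, so different genes carried the 2 means. Tyrobp and Fcer1g are also genes of myeloid cells. The immediate early list had mean levels of 5.66 to 6.38 in the 3 adipose clusters other than the cycling-like one, which had 3.87, and of 1.55 to 2.30 in the 6 spleen clusters of T cells. In the B cell and myeloid cluster of the spleen library the immediate early list was at 4.23.

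Immediate early genes were higher in adipose, with a median log2 ratio of 1.38. Scaling is argued against as the whole cause, since the median relative to the median gene was still 1.17. Among cells with at least 3 of 10 cell cycle genes, 119 from adipose and 18 from spleen, the median log2 ratio was 2.75. This argues against the share of cycling cells as the whole cause, on few spleen cells. It cannot decide on a larger adipose share of another state richer in these genes, which stays open. The cycling-like cluster had the lowest list mean of the adipose clusters, 3.87 against 5.66 to 6.38. Collagenase digestion may contribute and cannot be told apart from tissue, because only adipose was digested; the heat shock list had a median log2 ratio of 0.22, which bears on heat shock alone. A difference between the tissues themselves stays open and untested, as does an effect of the treatment of part of the spleen sample.

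Natural killer cell genes were higher in adipose, with a median log2 ratio of 3.72. Natural killer cells, which the receptor and tetramer gate should remove, are argued against as the whole cause, since 583 adipose cells with at least 2 of Tyrobp, Fcer1g and Ncr1 had 0.889 times the summed level of Cd3d, Cd3e, Cd3g and Trac of the 1688 adipose cells with none. A higher share of cells with Tbx21 is argued against in the same sense, since among these cells, 1312 in adipose and 1699 in spleen, the median log2 ratio was 3.97. Reads shared between near-identical Klra genes remain possible for those genes but do not bear on Tyrobp or Gzmb. A larger adipose share of a state rich in these genes within iNKT1 cells stays open, as does an untested difference between the tissues. An effect of the treatment of part of the spleen sample was not tested either. The group of 234 spleen cells, 3.93% of the sample, had list and Gzmb levels of 1.43 and 1.49. The adipose cluster led by Fcer1g and Tyrobp, 29.4% of its sample, had 1.14 and 1.37. Their raised list genes differed, however, with Gzma in the spleen group alone and Ncr1 and Tyrobp in that adipose cluster alone, so they need not be the same state.

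Il4 was 22.7-fold higher in spleen. A candidate explanation is free RNA in the spleen library: the Il4 level of the B cell and myeloid cluster was 0.881 times that of the other spleen cells, whereas the ratios of Cd3d, Cd3e, Cd3g and Trac were at most 0.252. Whether spleen cells with T cell receptor response transcripts were the source stays open: cells with none of 6 response genes, 73.9% of spleen cells, held 60.8% of the spleen Il4 corrected counts, at a level of 1.36 against 2.31 in the others, but the bound set for this test was wrong, since free RNA would lie in all cells whatever its source and undetected genes can be expressed. The Il4 level still varied 1.77-fold over the 6 spleen clusters of T cells, from 0.971 to 1.72, and its share of cells from 28.6% to 53.5%, so that some expression by the cells stays open, as do doublets of iNKT cells with other cells among the 43, most of which held Cd3d and Cd3g transcripts.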
